A study of Mus musculus with 305 samples.

How the data were processed

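Total RNA was taken from 6 brain regions of 51 male wild-type mice, and per the labels it was extracted with a Qiagen RNEasy Micro kit and made into strand-specific, ribosomal RNA-depleted libraries with the TruSeq Gold kit, sequenced as 2 ends of 150 bp. FastQC, HISAT2, SAMtools and HTSeq were used with genome build mm10, per the submitters' processing notes, which give no versions, settings or annotation release. The values used here are the raw read counts per Ensembl gene and library that the authors deposited in 1 table; the values themselves are whole numbers, and no normalization of them is recorded. The other 7 deposited files were not used here, and 0 value columns of the table lacked a sample. The table holds 52636 genes, of which 45431 had a count in at least 1 library and 52403 had a symbol in GENCODE M21 (GRCm38, which corresponds to mm10), 147 of them sharing a symbol with another gene. Gene names and coordinates come from that annotation, which may not be the release the authors used.

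Each region had 51 libraries, and BLA 50, because the BLA library of S24 mouse 37 was not analysed here. Groups were taken from the labels: per region 8 S24 (7 in BLA), 11 H24 and 8 each of SS, SH, HS and HH. Every H24 and S24 library of BLA carries 1 sample code set and the 30 d groups carry 2 others, so the early and the late groups were not compared. The mouse set named below is this code set, taken from the BLA library of a mouse and used for all its regions. Sets 1 and 2 held 6 and 2 HH mice, 6 and 2 HS mice, 4 and 4 SH mice, and 3 and 5 SS mice. Heroin history was thus partly bound up with the set. The median total per library was 34.14 M counts in BLA, 30.69 M in dStri, 31.63 M in NAc, 30.79 M in PFC, 30.95 M in vHPC and 31.24 M in VTA. All libraries but 1 held at least 19.31 M; the exception, VTA HH mouse 7, held 0.8899 M. Over 1163 pairs of libraries of the same group and region, the lowest chi-square per degree of freedom was 7.072 and the median 36.01, where counting noise alone gives 1 and separate mice are expected to exceed it. A library was said to stand apart when its median rank correlation with the other libraries of its region lay over 4 scaled median absolute deviations below the median of the region.

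Counts were analysed in R 4.3.3 within each region, separately for the 24 h and the 30 d mice. Genes were kept with edgeR's filter at a minimum count of 10 in the smallest group, scaled with TMM factors and fitted with the quasi-likelihood model of edgeR 4.0.16, with 1 coefficient per group. Contrasts were H24 against S24, SH, HS and HH against SS, HH against SH, and the interaction (HH minus SH) minus (HS minus SS). The p-values were adjusted per region and contrast by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Log2 values carry a prior count of 1. Direction counts give the libraries of the group named first that lie above or below the mean log2 CPM of the reference group. Contrasts, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The challenge and the history contrasts, 16 mice against 16 from the same fit, were added after the results were seen.

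The rule for named genes took, per region and contrast, from the called genes with a mean of at least 1 CPM and a symbol that is not a clone or model name, the 3 higher and the 3 lower with the smallest p, all called members of the 13 process lists up to 4 per list, and Oprm1, Fos, Fkbp5 and Ttr whether or not they were called. Because few genes were called, a rule added after the results were seen also names up to 2 higher and 2 lower genes per region with the smallest p (1 and 1 for HH against SH, the interaction and the history contrast, none for the challenge contrast). Other called genes of PFC, and list members that passed adjusted over the list alone, were chosen after their values were seen.

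The 13 process lists were immediate early genes, glucocorticoid-responsive genes, circadian clock genes, opioid peptides and receptors, dopamine signalling, glutamate receptor, GABA signalling, neuropeptide, extracellular matrix and perineuronal net, hypoxia and glycolysis, heat shock and chaperone, and interferon and inflammation genes, and DNA and chromatin modifiers. The 14 cell type lists held markers of oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia, endothelial and mural cells, choroid plexus, ependyma, meningeal fibroblasts, blood, striatal projection neurons, cortical and hippocampal excitatory neurons, dopamine neurons, midbrain, thalamic and hypothalamic neurons and cortical interneurons. All 494 list genes were in the table. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated for each list, adjusted over 27 lists and 6 regions per contrast. Members were also adjusted over their list alone. A score is the mean log2 CPM of a list's members in a library. Score differences of the challenge contrast were tested with 100000 permutations of the mice, for the immediate early, meningeal, and heat shock and chaperone lists only. These p-values were adjusted over the 6 regions within each list and not over lists.

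Differences of an effect between regions were tested across all libraries of a time point with voom in limma. Mouse numbers pair the libraries of different regions, since the labels give the same animal; deviations from the group means correlated at a mean r of 0.0158 between regions of the same mouse at 24 h and 0.0128 at 30 d, against -0.00174 and -0.00183 between different mice. The test between regions was therefore also run with the mouse as a replicate block. Groups within a region hold different mice, so no pairing applies there. The correlation of log2 values between regions was set against 100 joint regroupings of the mice, and SH and HH against SS, which share controls, against 200 simulated draws of unchanged groups and 70 splits of the SS mice.

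Alternatives were DESeq2 1.42.0 on its own size factors, RLE factors in edgeR, no low-count filter, oligodendrocyte and choroid plexus scores as covariates, library quality weights in limma, no libraries that stand apart, the mouse set as a covariate, an unadjusted p under 0.05 with a fold of at least 1.3, the replicate block, an estimated correlation for the lists, and genes of at least 5 CPM for the correlations. Added later were inflammation and meningeal scores as covariates, single libraries left out in NAc, PFC and dStri, VTA without HH mouse 7, vHPC without the libraries nearest to BLA, and 1 value per mouse averaged over regions. For each region and contrast the mice were also regrouped 60 times at random within their time point. The package data.table (version 1.17.8) read the deposited values.

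The code was run on simulated data with 200 changed genes per comparison, 50 at each fold. It recovered 22 to 70% at a fold of 1.3, 52 to 84% at 1.5, 78 to 96% at 2 and 94 to 100% at 3. In PFC, SH against SS gave 48, 74, 92 and 100%, with 7 false calls among 164. With few calls, as in the real tests, the threshold is stricter and recovery may be lower. A simulated list shifted in PFC had p = 2.29e-22 with the preset and p = 9.94e-12 with an estimated correlation by camera, and an unshifted list p = 0.774 and p = 0.747. The simulated genes were independent, so this run cannot tell how either setting does on lists whose members move together. The test between regions made 208 calls and recovered 194 of 200 changed genes, at an assumed dispersion.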

Results

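Bulk RNA-seq libraries were made from 6 brain regions of 51 male wild-type mice that had given themselves either heroin, an opioid agonist, or saline through an intravenous line for 15 d. The regions carry the labels BLA, NAc, PFC, VTA, dStri and vHPC, which in this field stand for basolateral amygdala, nucleus accumbens, prefrontal cortex, ventral tegmental area, dorsal striatum and ventral hippocampus. At 24 h of withdrawal 8 saline mice (S24) and 11 heroin mice (H24) were taken. The other 32 mice spent 30 d in withdrawal, then received a saline or heroin challenge and were placed in a drug-seeking test of 2 h. Their groups of 8 are named by the drug taken first and the drug given as challenge: SS, SH, HS and HH. The series asks which transcripts mark heroin intake and which mark relapse across the reward circuitry. Each region has 51 libraries, except BLA with 50, since the BLA library of S24 mouse 37 was not analysed here. The total per library ran from 0.89 to 61.35 M counts with a median of 31.42 M. The lowest was the VTA library of HH mouse 7. The next lowest held 19.31 M.

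The libraries carried the transcripts of the region they are named for. Dopamine neuron markers had a median log2 CPM of 6.05 in VTA and between -1.37 and -0.90 in the other regions. Striatal projection neuron markers stood at 8.49 in dStri and 7.86 in NAc, against 4.90 in BLA and between 1.92 and 2.65 in the other regions. No list held markers particular to BLA. Cortical and hippocampal excitatory neuron markers stood at 6.50 in PFC, 6.12 in vHPC and 5.71 in BLA, against 1.21 in NAc. All but 3 libraries lay nearest to the median profile of their own region. The 3, all nearest to BLA, were VTA HH mouse 7, vHPC SS mouse 28 and vHPC SH mouse 27. In the VTA library of HH mouse 7 the 10 most abundant genes took 73.9% of the counts. It and the libraries BLA H24 mice 39 and 42, BLA SS mouse 6, dStri HS mouse 11 and vHPC HH mouse 18 stood apart from the rest of their region.

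Single genes separated the treatment groups in few of the planned comparisons. Of 36 region-by-contrast tests on 17955 to 19976 genes each, 34 called no gene with edgeR at an adjusted p of 0.05, with 374 to 1811 genes per test at an unadjusted p under 0.05. DESeq2 called 0 to 27 genes per test. The 4 calls, all for a first heroin challenge (SH against SS), were Acer2 in NAc and Acer2, Dio2 and Zswim6 in PFC. Oprm1, which encodes the mu opioid receptor, differed by log2 values between -0.40 and 0.29 over 48 tests, with a smallest adjusted p of 0.663 by edgeR. Fkbp5, a glucocorticoid-induced co-chaperone, ranged from -0.06 to 0.19 and had a smallest adjusted p of 0.619.

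After 24 h of heroin withdrawal, blood markers as a list were higher in H24 than in S24 mice in 5 of the 6 regions, and choroid plexus markers in BLA and vHPC, by a list test that did not hold with an estimated correlation (smallest adjusted p = 0.385 with an estimated correlation). The median log2 difference of the blood markers was 0.82 in BLA, 0.40 in NAc, 0.44 in PFC, 0.73 in dStri and 0.74 in vHPC. Of the H24 libraries, the blood score lay above the S24 mean in 10 of 11 in BLA and dStri, 8 of 11 in PFC and vHPC, and 7 of 11 in NAc. All 15 measured choroid plexus markers in BLA (median 3.18) and all 13 in vHPC (median 3.99) were higher, with the score above the S24 mean in 8 of 11 libraries of both regions. In VTA all 12 meningeal fibroblast markers were lower, with a median of -0.675 and 11 of 11 H24 libraries under the S24 mean. There S24 mouse 37 held 20.7 CPM of Slc22a6, a member of this list, against 0.864 to 3.08 in the other S24 mice. That library may raise the S24 mean, and the list was not tested without it.

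These list differences rested on camera with a preset correlation between genes. Over 27 lists and 6 regions, 42 of 162 list tests passed with it and 0 passed with an estimated correlation, where the smallest adjusted p = 0.385. The blood call in BLA went from an adjusted p of 1.23e-08 to 0.385 with an estimated correlation. The choroid plexus call in vHPC went from 0.000208 to 0.707. Adjusted over the list alone, 6 blood genes passed in BLA, 2 in NAc, 5 in PFC, 4 in dStri and 3 in vHPC. In NAc the 12 measured markers of cortical and hippocampal excitatory neurons were lower (median -0.99, 11 of 11 libraries). Of these, 8 passed adjusted over the list alone, among them Camk2a, Neurod6 and Slc17a7, and the list had an adjusted p = 6.07e-05 with the preset and an adjusted p = 0.385 with an estimated correlation. In dStri the list of opioid peptides and receptors had a median of -0.19 and was lower in 10 of 11 libraries. Its members Oprk1, the kappa opioid receptor, and Pdyn, the dynorphin precursor, passed adjusted over the list alone (list adjusted p = 0.00696 with the preset, adjusted p = 0.385 with an estimated correlation). Of the 22 measured interferon and inflammation genes in BLA, 4 passed adjusted over the list alone (C3, Ifitm3, Bst2 and Ifi27), all higher in H24, and the score was higher in 8 of 11 libraries (list adjusted p = 0.000104 with the preset, adjusted p = 0.385 with an estimated correlation).

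No gene passed over all genes tested for H24 against S24 with edgeR in any region, where 454 to 1430 genes per region had an unadjusted p under 0.05 and DESeq2 called 0 to 27 per region, 41 in all. The named genes did not pass and are given as log2 difference ± SE. NAc came nearest: there Yipf3, a Golgi membrane protein, differed by -0.58 ± 0.106 and Tfip11, a splicing factor, by -0.42 ± 0.0785, both lower in 11 of 11 libraries (adjusted p = 0.11, edgeR). Casd1 (0.18 ± 0.045), a sialic acid acetyltransferase, and Klhl13 (0.28 ± 0.0701), a ubiquitin ligase adaptor, were higher in 11 of 11 NAc libraries with adjusted p = 0.232. In dStri, Depp1 was 1.22 ± 0.253 higher in 11 of 11 libraries and Cux2, a factor of upper cortical layers, differed by -0.59 ± 0.123, lower in 11 of 11 (both adjusted p = 0.36). S100a10 (0.50 ± 0.11) and Ak5 (-0.48 ± 0.11) in dStri also moved one way in 11 of 11 libraries, with adjusted p of 0.553 and 0.57. In VTA, Slc22a6, an organic anion transporter on the meningeal list, differed by -1.91 ± 0.429 and Trh, the thyrotropin-releasing hormone precursor, by -3.64 ± 0.864. Rbm3, a cold-inducible RNA-binding protein, differed there by 0.28 ± 0.077 and Gclm, an enzyme of glutathione synthesis, by 0.22 ± 0.0617 (all 4 adjusted p = 0.975, 10 or 11 of 11 libraries in the direction given).

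In BLA the leading named genes were Tc2n (3.95 ± 0.954), Ccl6 (1.02 ± 0.253), a chemokine, Cdhr1 (-0.90 ± 0.241) and Amz1 (-0.29 ± 0.0865), each in 10 or 11 of 11 libraries and with adjusted p = 0.641 by edgeR. In PFC they were the histone gene Hist1h2bg (-0.44 ± 0.117), the ribosomal protein gene Rpl10 (-0.26 ± 0.0721), Hdac9 (0.22 ± 0.0618), a histone deacetylase, and mt-Nd5 (0.40 ± 0.112), a mitochondrial subunit of respiratory complex I, all with adjusted p = 1 and 10 or 11 of 11 libraries. In vHPC, Mfrp differed by 5.18 ± 1.49, Ggt1 by 0.75 ± 0.208, Mir6236 by -2.71 ± 0.716 and Trmt5 by -0.28 ± 0.0806, in 9 to 11 of 11 libraries (adjusted p = 1). Ttr, the transthyretin gene that choroid plexus expresses at high level, was higher by 5.58 ± 1.77 in vHPC (9 of 11 libraries, adjusted p = 1) and by 3.27 ± 1.25 in BLA (8 of 11, adjusted p = 0.666). Single S24 libraries lay outside the range of their group for Slc22a6 and Trh in VTA (mouse 37), Casd1 in NAc, Ccl6 in BLA and Mir6236 in vHPC (mouse 46), and mt-Nd5 in PFC (mouse 50). The H24 groups were not searched for such libraries. Trh turned to a log2 value of 0.20 once the meningeal score was held constant.

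A first heroin challenge in mice with a saline history (SH against SS) lowered Acer2, the gene of an alkaline ceramidase that cleaves ceramides to sphingosine, in PFC and NAc, and raised Dio2 and Zswim6 in PFC. Acer2 stood at 13.6 ± 3.07 CPM in SS and 6.36 ± 1.06 CPM in SH mice in PFC (mean ± SD, n = 8 each), a log2 change of -1.10 ± 0.165 (SE) seen in 8 of 8 libraries (adjusted p = 0.00126, edgeR). In NAc it stood at 19.96 ± 3.797 CPM in SS and 11.3 ± 1.84 CPM in SH, a log2 change of -0.82 ± 0.145 in 8 of 8 libraries (adjusted p = 0.035). Dio2, the deiodinase that makes the active thyroid hormone within brain cells, went from 121.9 ± 17.07 to 176.8 ± 23.15 CPM in PFC (log2 0.54 ± 0.0951, 8 of 8, adjusted p = 0.011). Zswim6, a zinc finger protein gene, went from 32.1 ± 1.68 to 40.5 ± 3.00 CPM (log2 0.33 ± 0.0584, 8 of 8, adjusted p = 0.011). On GRCm38, Acer2 (ENSMUSG00000038007) spans chromosome 4 from 86874396 to 86934822 on the plus strand. Dio2 (ENSMUSG00000007682) lies on chromosome 12 from 90724552 to 90738438 and Zswim6 (ENSMUSG00000032846) on chromosome 13 from 107724617 to 107890064, both on the minus strand.

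The NAc call lay near the threshold: it ended when any of HH mouse 1, HS mice 3 and 11, SH mice 10, 19, 24, 27 and 30 or SS mice 8, 15, 22, 26 and 28 was left out. Without SS mouse 6 there were 2 genes. The 3 PFC genes became 2 to 15 when 1 library was left out (15 without SS mouse 22). They became 1 with oligodendrocyte and choroid plexus scores or with the meningeal score as covariates, and 0 with the inflammation score. Each of these covariates ended the NAc call.

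Immediate early genes, which neurons transcribe within minutes of activity, were higher in SH than in SS mice in PFC, NAc and dStri. In PFC 28 of 30 were higher with a median log2 difference of 0.26, and 18 passed adjusted over the list alone. The score lay above the SS mean in 7 of 8 libraries (adjusted p = 3.96e-23 with the preset, adjusted p = 0.115 with an estimated correlation). In NAc 26 of 30 were higher (median 0.25, 6 of 8 libraries, adjusted p = 6.66e-13 with the preset and adjusted p = 0.231 with an estimated correlation) and 5 passed adjusted over the list alone: Dusp6, Fos, Nr4a3, Fosl2 and Dusp4. In dStri 23 of 30 were higher (median 0.14, 8 of 8 libraries, adjusted p = 9.62e-06 with the preset, adjusted p = 0.385 with an estimated correlation). Fos itself differed by 0.79 ± 0.248 in NAc (6 of 8 libraries), 0.41 ± 0.139 in PFC (8 of 8) and 0.34 ± 0.136 in BLA (8 of 8), with adjusted p of 1, 0.589 and 0.999 by edgeR over all genes.

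Several cell type lists moved beside them in PFC. All 12 meningeal fibroblast markers were lower in SH (median -0.71, 8 of 8 libraries), 10 of them past the threshold adjusted over the list alone (adjusted p = 2.92e-17 with the preset, adjusted p = 0.115 with an estimated correlation). In VTA the same list went the other way, with 11 of 12 higher (median 0.577, 8 of 8 libraries, adjusted p = 7.05e-06 with the preset, adjusted p = 0.385 with an estimated correlation). All 15 oligodendrocyte markers were lower (median -0.53, 7 of 8 libraries) and 8 passed adjusted over the list alone, among them Mobp and Mog (adjusted p = 4.45e-12 with the preset, adjusted p = 0.385 with an estimated correlation). Endothelial and mural markers were lower by a median of -0.19 in 8 of 8 libraries (adjusted p = 1.14e-07 with the preset, adjusted p = 0.19 with an estimated correlation). Of the 24 measured interferon and inflammation genes 20 were lower, 3 of them past the threshold adjusted over the list alone: Ifitm3, the acute-phase gene Lcn2 and the complement gene C4b. The score was lower in 6 of 8 libraries (adjusted p = 6.16e-05 with the preset, adjusted p = 0.184 with an estimated correlation). Of 29 glucocorticoid-responsive genes 23 were lower (median -0.11, 8 of 8 libraries, adjusted p = 1.29e-05 with the preset, adjusted p = 0.19 with an estimated correlation). In dStri 13 of 14 cortical and hippocampal excitatory neuron markers were higher (median 2.13, 6 of 8 libraries, adjusted p = 4.15e-13 with the preset, adjusted p = 0.19 with an estimated correlation). Over all lists and regions 47 of 162 tests passed with the preset and 0 with an estimated correlation.

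Other named genes of this comparison did not pass over all genes tested. Lcn2 in PFC was nearest, at -1.55 ± 0.308 and lower in 8 of 8 libraries (adjusted p = 0.0579, edgeR). In dStri, Acer2 differed by -0.64 ± 0.143 and Osmr, the oncostatin M receptor, by -0.50 ± 0.108, both lower in 8 of 8 libraries, and Vxn by 2.29 ± 0.512 in 5 of 8 (adjusted p = 0.283 each). Mfsd4a in dStri differed by 0.42 ± 0.0839 in 8 of 8 (adjusted p = 0.27). In NAc, Xdh, the xanthine dehydrogenase gene, differed by -0.47 ± 0.0966 in 8 of 8 (adjusted p = 0.228), Fgfr2 by 0.26 ± 0.0648 in 8 of 8 and Fosl2 by 0.67 ± 0.17 in 7 of 8 (adjusted p = 1 for both). In BLA the complement gene C3 (-1.996 ± 0.471) and the interleukin-1 receptor gene Il1r1 (-0.68 ± 0.177) were lower and Glyctk (0.78 ± 0.231) higher in 8 of 8 libraries, and Papln (0.81 ± 0.24) higher in 7 of 8 (adjusted p = 0.999). In VTA, Coch (0.91 ± 0.233) and Enpp3 (1.07 ± 0.286) were higher and Dnah14 (-0.73 ± 0.215) lower in 8 of 8, and Cdh23 (-1.13 ± 0.336) lower in 7 of 8 (adjusted p = 1). In vHPC, Zfp874b (0.27 ± 0.0744), Palmd (-0.38 ± 0.106) and the interferon-induced Gbp3 (-0.62 ± 0.192) moved one way in 8 of 8 and Fbxw17 (0.36 ± 0.107) in 7 of 8 (adjusted p = 1). A single SS library lay outside its group for Cdh23 in VTA (mouse 28) and for Vxn in dStri (mouse 22), and a single SH library for Fos in BLA (mouse 30).

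In the regions BLA, VTA, dStri and vHPC no gene passed for SH against SS with edgeR, where 633, 661, 1077 and 462 genes had an unadjusted p under 0.05. DESeq2 called 24 genes over the 6 regions: 16 in PFC, 6 in dStri and 2 in NAc.

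A heroin history followed by a saline challenge (HS against SS) gave no called gene after 30 d: none passed with edgeR in any region, 410 to 732 genes per region had an unadjusted p under 0.05, and DESeq2 called 0. Over the lists 29 of 162 tests passed camera with the preset and 0 with an estimated correlation, where the smallest adjusted p = 0.788. The cortical and hippocampal excitatory neuron markers in VTA were lower by a median of -0.39 in 7 of 8 HS libraries, with Neurod2 and Slc17a7 past the threshold adjusted over the list alone (adjusted p = 0.0291 with the preset, adjusted p = 0.788 with an estimated correlation).

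The named genes of HS against SS had edgeR adjusted p values of 0.979 to 1. In BLA the serotonin receptor gene Htr1f (0.40 ± 0.109, 8 of 8 libraries) and the kinase gene Camk1g (0.37 ± 0.111, 7 of 8) were higher, and Lrrc32 (-0.95 ± 0.273) and Adssl1 (-0.63 ± 0.185) lower in 8 of 8. In NAc Lacc1 (0.63 ± 0.17) and Vsig10l (1.02 ± 0.282) were higher and Ccdc34 (-0.42 ± 0.0962) and the collagen gene Col23a1 (-0.60 ± 0.149) lower, each in 8 of 8. In PFC the spliceosome cyclophilin Cwc27 (0.36 ± 0.1) and Pqbp1 (0.19 ± 0.0525) were higher in 8 of 8, and Igip (-0.28 ± 0.0758) and Tmem245 (-0.23 ± 0.0633) lower in 7 of 8. In VTA Xlr3a (0.96 ± 0.246, 8 of 8) and the mitochondrial import factor Dnajc19 (0.31 ± 0.079, 7 of 8) were higher, and Impg2 (-0.92 ± 0.27, 8 of 8) and Tcf7 (-0.76 ± 0.223, 7 of 8) lower. In dStri the zinc transporter Slc39a8 (0.69 ± 0.167, 7 of 8) and the actin-nucleating subunit Arpc1b (0.32 ± 0.0767, 8 of 8) were higher, and Plagl2 (-0.50 ± 0.13) and Morc4 (-0.53 ± 0.147) lower in 8 of 8. In vHPC Eri2 (0.38 ± 0.104) and Nudt13 (0.29 ± 0.0806) were higher and Taf3 (-0.44 ± 0.129) and the mitochondrial iron importer Slc25a37 (-0.35 ± 0.106) lower, each in 8 of 8. One library lay outside its group for Col23a1 (SS mouse 32), Igip (SS mouse 31), Slc39a8 (SS mouse 22), Dnajc19 (HS mouse 13) and Impg2 (HS mouse 2). Without SS mouse 32, 1 gene passed in NAc.

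Mice with a heroin history that were challenged with heroin again (HH against SS) showed higher immediate early genes in PFC than mice that took and received saline. In PFC 28 of 30 measured members were higher with a median log2 difference of 0.31, in 8 of 8 libraries, and 16 passed adjusted over the list alone, among them Fos, Fosb, Arc, Egr1, Egr2 and Bdnf. This was the only list test of the 5 pairwise contrasts that held with an estimated correlation (adjusted p = 2.53e-33 with the preset, adjusted p = 0.0156 with an estimated correlation). The list was also higher in dStri, with 30 of 30 members higher and a median of 0.22 in 8 of 8 libraries (adjusted p = 1.58e-15 with the preset, adjusted p = 0.152 with an estimated correlation). In NAc 27 of 30 were higher (median 0.23, 7 of 8 libraries, adjusted p = 5.44e-12 with the preset, adjusted p = 0.358 with an estimated correlation). In PFC all 12 meningeal fibroblast markers were lower (median -0.63, 7 of 8 libraries), 4 of them past the threshold adjusted over the list alone (adjusted p = 1.63e-11 with the preset, adjusted p = 0.207 with an estimated correlation). In BLA 7 of 7 measured dopamine neuron markers were higher (median 0.62, 7 of 8 libraries, adjusted p = 1.81e-05 with the preset, adjusted p = 0.207 with an estimated correlation), with Slc6a3, the dopamine transporter gene, far higher in HH mouse 16 than the 1.01 CPM that the other 7 HH mice reached at most.

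No single gene passed for HH against SS with edgeR, where 400 to 1811 genes per region had an unadjusted p under 0.05 and DESeq2 called 17 over the 6 regions. In PFC the AP-1 gene Fosl2 (0.40 ± 0.0775) and Egr2 (0.80 ± 0.159) were higher in 8 of 8 libraries with adjusted p = 0.112, and Acer2 (-0.69 ± 0.162, adjusted p = 0.257) and the smooth muscle actin gene Acta2 (-0.83 ± 0.216, adjusted p = 0.586) were lower in 7 of 8. In NAc Cdkl4 (-0.62 ± 0.117, adjusted p = 0.121) was lower in 8 of 8, the interferon receptor gene Ifnar2 (-0.33 ± 0.0863) lower and Mbd3 (0.61 ± 0.155) and Zw10 (0.26 ± 0.0683) higher in 8 of 8 (adjusted p = 0.999). In dStri Pthlh (0.52 ± 0.139) and Nr4a3 (0.48 ± 0.129) were higher and Zkscan14 (-0.32 ± 0.0765) and Fam3a (-0.28 ± 0.0927) lower in 8 of 8 (adjusted p = 1). In vHPC Mtmr11 (0.71 ± 0.163) was higher and Parvb (-0.60 ± 0.152) and Zfp11 (-0.43 ± 0.111) lower in 8 of 8, and Nudt13 (0.31 ± 0.0807) higher in 7 of 8 (adjusted p = 0.515). In BLA Ptpdc1 (0.28 ± 0.0785) was higher and Fam124a (-0.40 ± 0.0862) and Col1a1 (-1.08 ± 0.32) lower in 8 of 8, while Slc6a3 (4.00 ± 0.994) was higher in 4 of 8 (adjusted p = 1). DESeq2 gave Slc6a3 a log2 value of -0.40, with the opposite sign.

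In VTA the leading values of HH against SS rested on the shallow library of HH mouse 7. The mitochondrial genes mt-Nd6 (8.00 ± 1.47, 5 of 8 libraries) and mt-Nd5 (5.22 ± 1.04, 4 of 8) led with adjusted p = 0.0846 by edgeR, and mouse 7 had 164100 and 147200 CPM of them against at most 98.5 and 600 in the other 7 HH mice. Without that library mt-Nd5 differed by -0.0015 and mt-Nd6 by 0.0566. Frrs1 (-0.86 ± 0.244, adjusted p = 0.655) and the chemokine gene Ccl9 (-0.80 ± 0.243, adjusted p = 1) were lower in 8 of 8, with a count of 0 in mouse 7, and differed by -0.8545 and -0.7989 without it. Beyond VTA, single SS libraries lay outside their group for Fam124a in BLA and Mbd3 in NAc (mouse 26) and Zfp11 in vHPC (mouse 31), and single HH libraries for Fos in NAc (mouse 25) and Nr4a3 in dStri (mouse 7). In PFC the count of 0 became 4 without HS mouse 13 and 3 without any of HH mice 5 and 25, HS mouse 11, SH mouse 17 and SS mouse 8. It became 2 without HS mice 2 or 14 and 1 without HS mouse 20 or SS mouse 6. In NAc it became 1 without SS mouse 26.

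Between the heroin-challenged groups, HH against SH asks what a heroin history adds to the challenge. Choroid plexus markers were higher in HH in vHPC, with 15 of 15 members higher and a median of 3.55, though in 5 of 8 libraries (adjusted p = 2.78e-05 with the preset, adjusted p = 0.672 with an estimated correlation). In vHPC 14 of 18 dopamine signalling genes were lower (median -0.35, 6 of 8 libraries), and 6 of them passed adjusted over the list alone, among them Drd2 and Adora2a (adjusted p = 0.000214 with the preset, adjusted p = 0.651 with an estimated correlation). In vHPC 11 of 13 striatal projection neuron markers were lower too (median -0.827, 6 of 8 libraries, adjusted p = 0.000324 with the preset, adjusted p = 0.651 with an estimated correlation), and 11 of the 20 dopamine signalling genes and 9 of the 15 striatal markers are shared with other lists. These values leaned on the vHPC library of SH mouse 27, 1 of the libraries nearest to BLA. Without it and SS mouse 28, the dopamine signalling median was -0.189 with 1 member, Slc6a3, past the threshold adjusted over the list alone (5 of 8 libraries lower, adjusted p = 0.017 with the preset, adjusted p = 0.706 with an estimated correlation), and the striatal median -0.253 (adjusted p = 0.0953 with the preset, adjusted p = 0.745 with an estimated correlation). The dopamine signalling score went the other way in NAc (higher in 8 of 8 HH libraries), VTA and dStri (7 of 8 each) and BLA (6 of 8). In dStri 12 of 14 cortical and hippocampal excitatory neuron markers were lower (median -1.39, 6 of 8 libraries, adjusted p = 2.48e-05 with the preset, adjusted p = 0.651 with an estimated correlation). Over the lists, 42 of 162 tests passed with the preset and 0 with an estimated correlation.

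No gene passed for HH against SH with edgeR, where 453 to 1441 genes per region had an unadjusted p under 0.05 and DESeq2 called 9 over the 6 regions. The nearest named genes were mt-Nd6 in VTA (8.14 ± 1.48, 7 of 8 libraries, adjusted p = 0.0707), set by HH mouse 7, and Cdkl4 in NAc (-0.61 ± 0.117, 8 of 8, adjusted p = 0.137). Mgat2 in VTA differed by -0.25 ± 0.0621 (8 of 8, adjusted p = 0.235), and Zfp11 in NAc by 0.31 ± 0.0868 (8 of 8, adjusted p = 1). In dStri Zfyve21 (0.34 ± 0.0776) and the chromatin remodeller Atrx (-0.24 ± 0.0559) moved one way in 8 of 8 (adjusted p = 0.755). In vHPC Slc6a3 differed by -1.84 ± 0.45 in 8 of 8 and Tmem134 by 2.03 ± 0.479 in 6 of 8 (adjusted p = 0.651). In PFC Tmem53 differed by 1.00 ± 0.265 in 8 of 8 and the pseudogene Rbm3-ps, whose reads may be shared with Rbm3, by -1.06 ± 0.298 in 7 of 8 (adjusted p = 0.999). In BLA Cstad differed by -1.05 ± 0.288 in 8 of 8, with SH mouse 10 outside its group, and Slc6a3 by 3.34 ± 0.952, higher in HH mouse 16 alone and negative by DESeq2 (-1.04). In NAc 1 gene passed without SS mouse 26.

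The interaction asks whether the challenge effect depends on the history. With edgeR no gene passed in any region, 374 to 951 genes per region had an unadjusted p under 0.05, and DESeq2 called 0. Direction is given here as the share of the 16 HH and SS libraries above or below the mean of the SH and HS libraries. In BLA C3 had an interaction of 2.68 ± 0.652 (14 of 16 above) and Mob3a of -0.80 ± 0.231 (14 of 16 below). In NAc Ppp1r3f stood at 0.67 ± 0.177 (16 of 16 above) and the mitochondrial ribosomal gene Mrps28 at -0.53 ± 0.17 (14 of 16 below). In PFC Palm2 stood at 0.48 ± 0.124 (14 of 16 above) and Cwc27 at -0.49 ± 0.142 (15 of 16 below). In dStri Tmco5 stood at 1.202 ± 0.34 (15 of 16 above) and Lyl1 at -1.16 ± 0.317 (16 of 16 below). In vHPC Prelp, a matrix proteoglycan, stood at 1.11 ± 0.335 (12 of 16 above) and Myo3b at -1.35 ± 0.376 (15 of 16 below). The edgeR adjusted p was 0.999 in vHPC and 1 in the regions named before it. In VTA mt-Nd6 (8.13 ± 1.74, 11 of 16 above) and Nars2 (-0.59 ± 0.129, 16 of 16 below), a mitochondrial aminoacyl-tRNA ligase, had an adjusted p of 0.537. Without HH mouse 7, where Nars2 had a count of 0, mt-Nd6 stood at 0.2029 and Nars2 at -0.5694. One library also lay outside its group for Mrps28 (SH mouse 17), Tmco5 (HH mouse 25), Myo3b (HS mouse 12) and Prelp (HS mouse 20). The cortical and hippocampal excitatory neuron markers of dStri had a median interaction of -2.24, with 12 of 14 below 0 (adjusted p = 9.86e-12 with the preset, adjusted p = 0.71 with an estimated correlation). Over the lists 30 of 162 tests passed with the preset and 0 with an estimated correlation.

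Averaging the challenge over both histories (SH and HH against SS and HS, 16 mice against 16) was chosen after the pairwise results were seen. In PFC 28 genes rose and 19 fell with the heroin challenge, with immediate early genes higher and meningeal markers lower as lists. Immediate early genes gave 13 of the 28. Dusp6 (0.37 ± 0.0527), a phosphatase that ERK signalling induces, had an adjusted p of 0.000175 by edgeR, Fosl2 (0.36 ± 0.0548) of 0.000296 and Egr2 (0.70 ± 0.113) of 0.000724, each higher in 16 of 16 challenged mice, and Fosb (0.50 ± 0.0798) was higher in 15 of 16 (adjusted p = 0.000724). Fos went from 36.0 ± 7.85 CPM in SS and 33.2 ± 11.7 in HS to 47.6 ± 4.49 in SH and 51.4 ± 7.69 in HH (mean ± SD, n = 8 each). Its log2 change was 0.52 ± 0.0983 in 16 of 16 mice (adjusted p = 0.00541). Bdnf (0.32), Nr4a1 (0.48), Arc (0.49), Nr4a3 (0.37), Egr1 (0.40), Trib1 (0.40), Egr3 (0.27) and Egr4 (0.42) also rose, in 14 to 16 of 16 mice with adjusted p from 0.000724 to 0.0235.

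Outside the immediate early genes, Zswim6 (0.33 ± 0.0413, adjusted p = 1.48e-05) and Dio2 (0.48 ± 0.0672, adjusted p = 0.000128) rose in 16 of 16 mice in PFC by edgeR. So did the neuropeptide gene Adcyap1, which encodes PACAP (0.25 ± 0.0451, adjusted p = 0.00265), and the clock gene Bhlhe40 (0.22 ± 0.0472, adjusted p = 0.0202). The heat shock gene Dnajb5 rose in 15 of 16 (0.30 ± 0.0533, adjusted p = 0.00223). Acer2 fell in 15 of 16 mice (-0.77 ± 0.115, adjusted p = 0.000296), and so did Dcn (-0.90 ± 0.148, adjusted p = 0.000973), the matrix proteoglycan decorin. Ptgds (-0.82 ± 0.144, adjusted p = 0.00223), a prostaglandin D synthase abundant in the meninges, fell in 16 of 16. Dcn, Apod, Col1a1 and Igf2 were the called members of the 12 meningeal markers. Further calls were C4b of the inflammation list (-0.58 ± 0.129, adjusted p = 0.0283) and Plekhf1 of the glucocorticoid list (-0.58 ± 0.129, adjusted p = 0.027), both lower in 15 of 16. One library lay outside its group for Dcn (HH mouse 5), Plekhf1 (SH mouse 4) and Fosb (SS mouse 28).

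**Figure D1:**
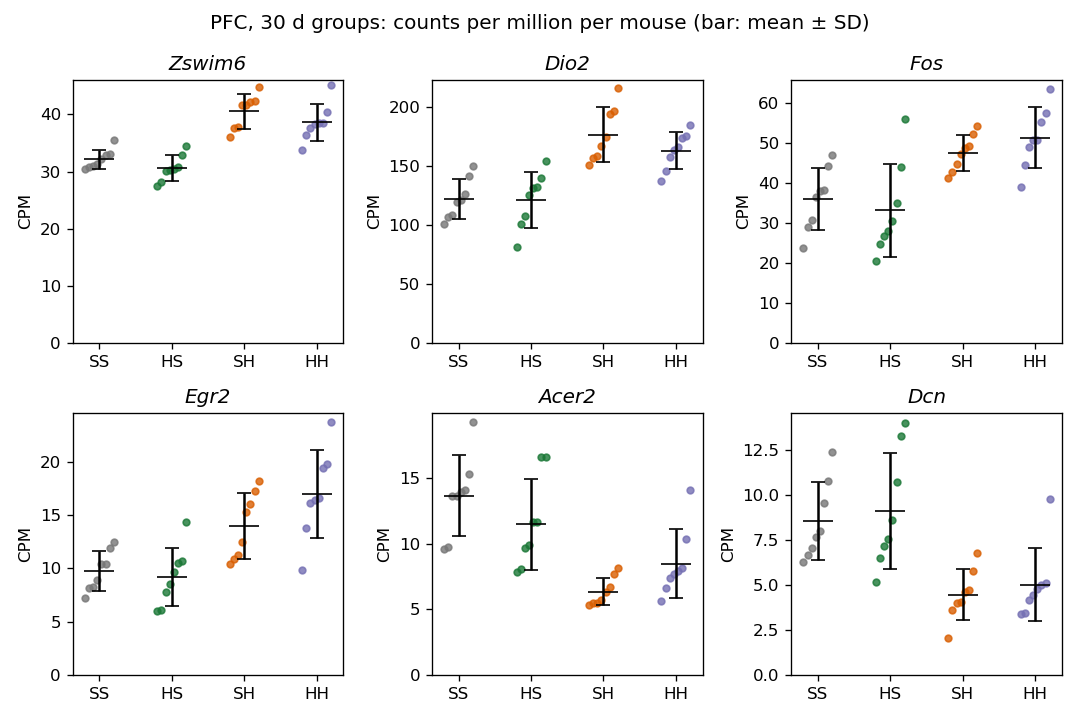
CPM (vertical axes, from 0) of 6 genes in PFC for the SS, HS, SH and HH mice, 8 points per group sorted by value within the group so that horizontal position has no meaning, with bars for mean ± SD. Zswim6, Dio2, Fos and Egr2 stand higher and Acer2 and Dcn lower in the heroin-challenged groups SH and HH; Fos averages 36.0 CPM in SS and 51.4 in HH.

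As lists, 29 of 30 immediate early genes were higher with the challenge in PFC (median 0.27), and 25 passed adjusted over the list alone. The score was higher in 16 of 16 challenged mice (adjusted p = 1.11e-51 with the preset, adjusted p = 0.000743 with an estimated correlation). All 12 meningeal fibroblast markers were lower there (median -0.78), all 12 past the threshold adjusted over the list alone, in 15 of 16 mice (adjusted p = 3.29e-26 with the preset, adjusted p = 0.0129 with an estimated correlation). These were the 2 of 51 preset calls over 162 tests that held with an estimated correlation. Of the 15 oligodendrocyte markers in PFC, 14 passed adjusted over the list alone and were lower (median -0.43, 13 of 16 mice, adjusted p = 7.35e-14 with the preset, adjusted p = 0.269 with an estimated correlation). Mean blood scores there were 1.49 in SH and 1.66 in HH, against 2.06 in SS and 2.1 in HS. Endothelial and mural scores were 3.87 and 3.91 against 4.06 and 3.99 in the same order. Cortical and hippocampal excitatory neuron scores went the other way, at 6.51 and 6.55 against 6.45 and 6.48. Interferon and inflammation genes were lower (20 of 24, median -0.205, 12 of 16 mice, adjusted p = 4.06e-06 with the preset, adjusted p = 0.0798 with an estimated correlation). Heat shock and chaperone genes were higher in 23 of 24 cases (median 0.09, 13 of 16 mice, adjusted p = 1.63e-08 with the preset, adjusted p = 0.234 with an estimated correlation).

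In NAc 15 of 30 immediate early genes passed adjusted over the list alone, 29 were higher (median 0.23) and the score was higher in 13 of 16 mice (adjusted p = 4.18e-22 with the preset, adjusted p = 0.0798 with an estimated correlation). In dStri 9 passed adjusted over the list alone, with 25 higher (median 0.17, 15 of 16 mice, adjusted p = 7.35e-14 with the preset, adjusted p = 0.114 with an estimated correlation). Cortical and hippocampal excitatory neuron markers stood higher beside them, 13 of 14 in NAc (median 0.966, adjusted p = 0.000117 with the preset, adjusted p = 0.549 with an estimated correlation) and 14 of 14 in dStri (median 1.10, adjusted p = 7.13e-06 with the preset, adjusted p = 0.441 with an estimated correlation), though their score was higher in 7 of 16 mice in each. All 24 heat shock and chaperone genes were higher in both regions, by medians of 0.08 in NAc and 0.14 in dStri and in 14 of 16 mice in each (adjusted p = 0.178 with an estimated correlation in both). Among them Dnajb1, Hspa1a and Hspa1b passed adjusted over the list alone in both regions, and 11 passed in dStri. Fos was higher by 0.72 ± 0.175 in NAc (13 of 16 mice, adjusted p = 0.296 by edgeR), 0.41 ± 0.0961 in BLA (16 of 16, adjusted p = 1) and 0.46 ± 0.122 in VTA (16 of 16, adjusted p = 0.804), and in these regions it passed adjusted over the list alone. Over all genes, NAc had 1 call, Acer2 (-0.63 ± 0.102, lower in 15 of 16 mice, adjusted p = 0.00771), and dStri had 1, the orphan nuclear receptor gene Nr4a3 (0.56 ± 0.0916, 16 of 16, adjusted p = 0.00836). The NAc call ended with the inflammation score as a covariate. Leaving out 1 library at a time gave 1 to 5 calls in NAc and 1 to 2 in dStri.

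**Figure D2:**
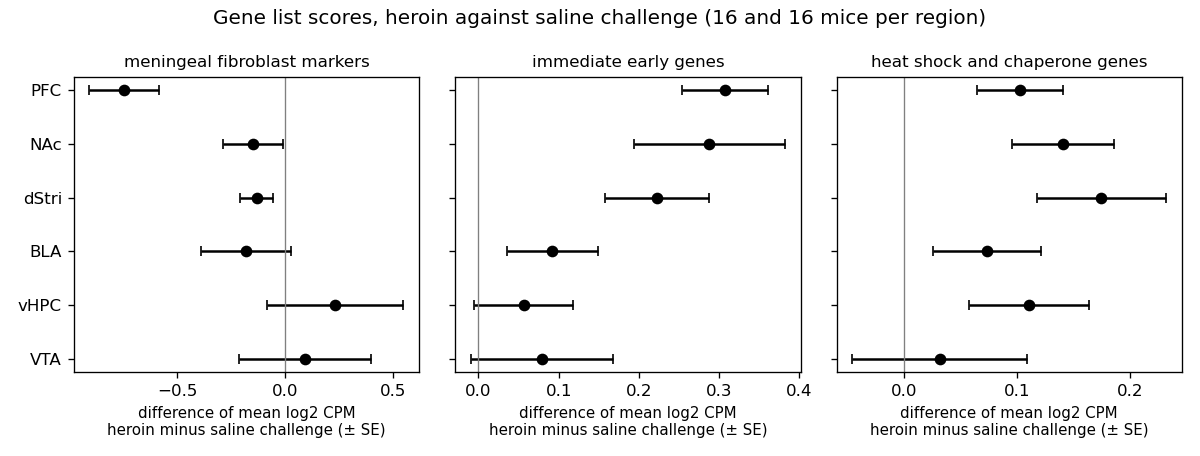
Difference in the mean log2 CPM of 3 gene lists between 16 heroin-challenged and 16 saline-challenged mice (horizontal axes, heroin minus saline, scaled separately for each list) in the 6 regions (vertical axis), as points with standard errors; VTA includes the shallow library of mouse 7. The meningeal score stands at -0.745 in PFC and the immediate early gene score at 0.307 in PFC, 0.288 in NAc and 0.223 in dStri.

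The score differences, tested per mouse with a permutation test adjusted over the 6 regions, were 0.307 ± 0.0536 for immediate early genes in PFC (adjusted p = 0.00012, 16 of 16 mice), 0.223 ± 0.0646 in dStri (adjusted p = 0.0036, 15 of 16) and 0.288 ± 0.0941 in NAc (adjusted p = 0.01, 13 of 16). The meningeal score differed by -0.745 ± 0.161 in PFC (adjusted p = 0.00018, 15 of 16), and with a permutation adjusted p of at least 0.29 in the other regions. The heat shock and chaperone score differed by 0.175 ± 0.0574 in dStri and 0.141 ± 0.045 in NAc (permutation adjusted p = 0.013 and 14 of 16 mice in each) and by 0.103 ± 0.0379 in PFC (permutation adjusted p = 0.022, 13 of 16), and its adjusted p was at least 0.066 in the other regions. In PFC the 47 calls became 23 with oligodendrocyte and choroid plexus scores, 9 with the meningeal score and 8 with the inflammation score as covariates, against 94 with library quality weights and 100 with DESeq2. They became 75 without SH mouse 29, 74 without HH mouse 5 and 73 without SH mouse 4. In BLA, VTA and vHPC no gene passed with edgeR, where 546, 611 and 466 genes had an unadjusted p under 0.05 and DESeq2 called 0.

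The mirror contrast of history (HS and HH against SS and SH), also added after the results were seen, called no gene with edgeR in any region, with 493 to 1518 genes per region at an unadjusted p under 0.05 and 2 DESeq2 calls in all. In vHPC 15 of 18 dopamine signalling genes were lower (median -0.245, 12 of 16 mice), and 6 passed adjusted over the list alone (adjusted p = 0.000596 with the preset, adjusted p = 0.705 with an estimated correlation). Striatal projection neuron markers were lower there too (12 of 13, median -0.572, 11 of 16 mice, adjusted p = 0.00172 with the preset, adjusted p = 0.705 with an estimated correlation). Both vHPC libraries nearest to BLA, SS mouse 28 and SH mouse 27, are in the reference groups. Without them the dopamine signalling median was -0.176 with 1 member past the threshold adjusted over the list alone (10 of 16 mice lower, adjusted p = 0.0164 with the preset, adjusted p = 0.703 with an estimated correlation), and the striatal median -0.195 (adjusted p = 0.115 with the preset, adjusted p = 0.772 with an estimated correlation). The dopamine signalling score was higher in NAc (15 of 16 mice), VTA (14 of 16), and BLA and dStri (11 of 16 each). All 16 endothelial and mural markers were higher in dStri (median 0.11, 10 of 16 mice, adjusted p = 7.07e-05 with the preset, adjusted p = 0.705 with an estimated correlation). The named genes did not pass by edgeR. They were Zfyve21 (0.24 ± 0.0548, 16 of 16 mice, adjusted p = 0.248) and Atrx (-0.15 ± 0.0395, 15 of 16, adjusted p = 0.609) in dStri, and Cdkl4 (-0.39 ± 0.0822, 15 of 16, adjusted p = 0.627) and Rhbdf1 (0.30 ± 0.0833, 14 of 16, adjusted p = 1) in NAc. In BLA Col1a1 (-1.05 ± 0.226) and Htr1f (0.33 ± 0.0771) moved one way in 16 of 16 (adjusted p = 0.837), with SH mouse 19 outside its group for Col1a1. In vHPC Tmem134 (1.34 ± 0.329, 13 of 16) and Gpr173 (-0.40 ± 0.1, 14 of 16) had adjusted p = 0.619, and in PFC Ccdc106 (0.24 ± 0.0594, 15 of 16) and Pnma1 (-0.34 ± 0.0901, 16 of 16) adjusted p = 1. In VTA mt-Nd6 (4.07 ± 0.871, 10 of 16, adjusted p = 0.812) and Chat, the choline acetyltransferase gene (-0.98 ± 0.267, 16 of 16, adjusted p = 1), led; without HH mouse 7, where Chat had a count of 0, they stood at 0.09633 and -0.9766.

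Whether a treatment effect differs between regions was tested for 24259 genes across the 30 d libraries. For SH against SS 1 gene passed, Tmprss7 (ENSMUSG00000033177), with an adjusted p of 0.00299 by limma. Its log2 value was 1.14 ± 0.333 in NAc (8 of 8 SH libraries higher), 1.23 ± 0.57 in dStri, 0.48 ± 0.293 in BLA and 0.24 ± 0.437 in vHPC, against -0.49 ± 0.173 in PFC and -1.42 ± 0.449 in VTA (8 of 8 lower in each), and its mean lay under 1 CPM in NAc, VTA, dStri and vHPC. For the challenge contrast no gene passed (smallest adjusted p = 0.139, 1014 genes at an unadjusted p under 0.05), so the PFC calls were not shown to be specific to PFC. The counts were also 0 for HS against SS, HH against SS, HH against SH, the interaction and the history contrast, with 681, 1478, 1303, 557 and 1790 genes at an unadjusted p under 0.05, and for H24 against S24 with 1018 of 23399 genes. DESeq2 was not run on this test.

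The log2 values of one contrast hardly correlated between regions across genes, which are not independent replicates. Over the 15 pairs of regions the median Pearson r was 0.0434 for SH against SS (permutation p = 0.03 from 100 joint regroupings of the mice), 0.0508 for HS against SS (p = 0.06), 0.0213 for HH against SS (p = 0.23), 0.0177 for HH against SH (p = 0.47) and 0.0123 for H24 against S24 (p = 0.65), and Benjamini-Hochberg adjustment over these 5 leaves none under 0.05. SH against SS and HH against SS share the SS libraries. Their r across genes was 0.447 in BLA, 0.589 in NAc, 0.521 in PFC, 0.229 in VTA, 0.536 in dStri and 0.394 in vHPC, where unchanged groups simulated against the same controls gave 0.446 to 0.5. With the SS mice split between both comparisons r was -0.11 to 0.0539. The covariance exceeded the simulated one by 0.00789 in NAc, 0.00724 in PFC and 0.00087 in dStri, and lay under it in BLA, VTA and vHPC. In every region it lay within the central 95% of the simulated values (0.0473 in NAc, for example, within 0.00962 to 0.0692). Without HH mouse 7, r in VTA was 0.482.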

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

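The regroupings of the mice, the test of single-library preparation, both tests of the meningeal pattern and the values of the 13 called immediate early genes were chosen after the results were seen, as were the challenge and history contrasts. A single library far outside the range of the others of its group was looked for in 458 sets of values, and 51 were found, where chance gives about 5 percent of the sets. The H24 groups, with 11 libraries each, were too large for this test and were not searched.

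The total counts stood outside the range of their group in 6 libraries: BLA S24 mouse 35 at 61.35 M (others 29.79 to 42.26), BLA SS mouse 22 at 43.6 M (31.24 to 36.17), PFC SS mouse 22 at 43.48 M (22.9 to 31.42), VTA HH mouse 7 at 0.8899 M (26 to 40.99), VTA SS mouse 32 at 51.07 M (25.59 to 35.92) and dStri HH mouse 5 at 22.91 M (32.13 to 36.51).

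In VTA HH mouse 7 the CPM stood at 147200 for mt-Nd5 (others 422 to 600), 164100 for mt-Nd6 (65.8 to 98.5) and 220.9 for Oprm1 (9.65 to 17.4), and at 0 for Ccl9 (0.728 to 1.63), Chat (0.607 to 1.15), Frrs1 (0.416 to 1.15) and Nars2 (10.9 to 13.7).

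Among S24 libraries, CPM of mouse 37 in VTA stood at 37.8 for Fkbp5 (others 16.9 to 24.1), 20.7 for Slc22a6 (0.864 to 3.08) and 123.8 for Trh (0.867 to 3.32). Mouse 46 stood at 99.2 for Casd1 in NAc (107.8 to 113.9), 0.302 for Ccl6 in BLA (0.572 to 0.851) and 0 for Mir6236 in vHPC (2.14 to 56.9). Fos stood at 7.19 in BLA of mouse 41 (9.6 to 11.2) and mt-Nd5 at 170 in PFC of mouse 50 (282.2 to 349.7).

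Among SS libraries, CPM stood at 120 for Cdh23 in VTA of mouse 28 (others 15.5 to 27.1), 5.97 for Fos in dStri (15.2 to 26.3) and 19.6 for Fosb in PFC (28.3 to 38.7) of the same mouse. It stood at 3.04 for Col23a1 in NAc of mouse 32 (5.44 to 8.31), 27.6 for Fam124a in BLA (17.2 to 21.4) and 30.1 for Mbd3 in NAc (14.5 to 19.8) of mouse 26, and 0.643 for Frrs1 in VTA of mouse 8 (1.35 to 2.1). In mouse 31 it stood at 51.2 for Igip in PFC (37 to 41.8) and 13.2 for Zfp11 in vHPC (9.35 to 10.6), in mouse 22 at 1.52 for Slc39a8 (2.21 to 2.96) and 34.4 for Vxn (11.4 to 17.6) in dStri, and in mouse 6 at 5480 for Ttr in BLA (9.28 to 169).

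Among SH libraries, CPM stood at 15.9 for Col1a1 (others 2.17 to 4.89) and 27.6 for Oprm1 (15.3 to 17.4) in BLA of mouse 19, 0.634 for Cstad in BLA of mouse 10 (1.21 to 2.13), 45.9 for Fos in BLA of mouse 30 (23.3 to 30.9), 5.19 for Mrps28 in NAc (7.43 to 10) and 502 for Ttr in BLA (14 to 54.6) of mouse 17, and 5.12 for Plekhf1 in PFC of mouse 4 (2.74 to 3.46). Among HS libraries it stood at 15.4 for Dnajc19 in VTA of mouse 13 (19 to 21.8), 5.58 for Fos in dStri of mouse 11 (13.4 to 27.5), 0.364 for Impg2 in VTA of mouse 2 (0.719 to 1.02), 0.437 for Myo3b in vHPC of mouse 12 (1.15 to 2.5), 29.8 for Prelp in vHPC of mouse 20 (16.9 to 21.9) and 10.8 for Ttr in PFC of mouse 23 (0.0522 to 0.767). Among HH libraries it stood at 9.78 for Dcn in PFC of mouse 5 (3.41 to 5.12), 10.3 for Fos in NAc of mouse 25 (18.8 to 30.9), 60.8 for Nr4a3 in dStri of mouse 7 (31.9 to 42.5), 116.5 for Slc6a3 in BLA of mouse 16 (0.472 to 1.01) and 0.657 for Tmco5 in dStri of mouse 25 (1.27 to 2.15).

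The effect of SH against SS differed between regions for 1 gene, Tmprss7, by a test of the difference itself.

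The inflammation score was partly shared by the regions of a mouse: the mouse took 0.291 of the variance of the group-centred score, most of which thus lay within mice (permutation p = 1e-05, the smallest 100000 permutations can give; highest permuted share 0.2; 49 mice). Preparation of single libraries would give no sharing, so it is not the source of the shared part, but with a share under 0.3 it stays open for the rest. Preparation by mouse stays open for the shared part. The blood score, whose 8 genes are not among the 30 of the inflammation list, rose and fell with it, with a median Spearman's rho of 0.524 over 6 regions (0.109 in PFC to 0.629 in BLA), as blood left in the tissue may give. Centring on the groups removes their mean differences, so treatment group is not a source of this sharing. Whether the uncentred score differs by group is another matter: the 4 groups took 0.203 of its variance between the 30 d mice (permutation p = 0.1), which decides neither way. Blood and an immune state of the mouse stay open for the sharing.

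In PFC the heroin challenge came with higher immediate early genes and lower meningeal genes. All 12 of 12 meningeal markers were lower, as less meningeal tissue in those samples may give. The mean score of the other 5 regions of the same mice differed by 0.026 ± 0.0864 (SE, 15 against 16 mice). This speaks against a change of the size in PFC (-0.745) shared by all regions. By region the score was lower in BLA (-0.179), NAc (-0.148) and dStri (-0.131) and higher in VTA (0.0924, mouse 7 included) and vHPC (0.233). A smaller change shared by some regions stays open. With the meningeal score as a covariate the 30 immediate early genes had a median log2 of 0.3, with the inflammation score 0.262, against 0.271 without, and within the mouse sets the smaller score difference was 0.289, so none of these 3 explains the whole list difference. Of the 13 called immediate early genes 2 were called with the meningeal score and 4 with the inflammation score. Over the 13 the median log2 went from 0.398 to 0.399 and 0.369, and the median SE from 0.0798 to 0.104 and 0.0909. All 11 and 9 lost calls had a larger SE, and 7 and 8 of them a smaller log2 value, so these calls ended with wider errors and partly with smaller values. Neural activity after the challenge stays a hypothesis for the list, and sampling of the meninges or a change in them stays open for the meningeal genes.

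When the mice were regrouped at random 60 times, the real grouping included, 1 grouping called as many genes as the 47 of the challenge in PFC (highest other 2). For the 1 gene of the challenge in NAc 1 grouping called as many (highest other 0), and for the 3 genes of SH against SS in PFC 2 did (highest other 4). Taken alone, each share is under 0.05, with the widest margin for the 47 genes. None of the shares is adjusted over the 48 tests, and both challenge counts come from a contrast chosen after the results. With 60 groupings per test, chance is therefore not excluded for the 1 gene in NAc and the 3 genes in PFC. Nor can it be excluded for the 1 gene of the challenge in dStri (3 of 60, highest other 5) or the 1 gene of SH against SS in NAc (6 of 60, highest other 23). Every count of 0 was reached by 60 of 60. In other groupings up to 1244 genes were called for HS against SS in vHPC, 470 for HH against SH in NAc, 333 for HH against SS in vHPC, 280 for HH against SS in BLA and 205 for the history in vHPC, which points to a structure among the samples other than treatment.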

How the results depend on the processing

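The inflammation and meningeal covariates, the libraries left out one at a time, VTA without HH mouse 7, vHPC without the libraries nearest to BLA and the tests of the challenge and history contrasts were chosen after the data were seen. RLE factors left all 48 counts of called genes within 1.5 times, the mouse set all 42 it could be fitted for, and leaving out the libraries that stand apart all 29. Without the vHPC libraries nearest to BLA (SS mouse 28 and SH mouse 27) edgeR called 0 genes in all 7 late contrasts of vHPC, as with them, with 465 to 2006 genes at an unadjusted p under 0.05. VTA without HH mouse 7 gave 0 called genes in all 7 late contrasts, as it did with that library, and the median r of SH and HH against SS over regions was then 0.502, against 0.484 with it. The replicate block left all 8 counts of genes differing between regions as they were, 1 for SH against SS and 0 by limma for the others (569 to 1827 genes at an unadjusted p under 0.05; DESeq2 was not run on this test). It was run on no other count. Beyond the immediate early genes of PFC, the cause of a moved count was not tested.

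With DESeq2, counts were 11 for H24 against S24 in BLA, 27 in NAc (4 up, 23 down) and 3 in dStri; 2 for SH against SS in NAc, 16 in PFC and 6 in dStri; 1 for HH against SS in NAc, 9 in PFC, 5 in VTA and 2 in vHPC; 1 for HH against SH in NAc, 7 in VTA and 1 in vHPC; 10 for the challenge in NAc, 100 in PFC (47 up, 53 down) and 8 in dStri; and 1 for the history in BLA and in vHPC. All 47 challenge genes of PFC were among the 100. Without a low-count filter they were 3 for H24 against S24 in NAc, 6 for SH against SS in PFC, 2 for HH against SS in PFC and 17 in VTA, 7 for HH against SH in VTA, 6 for the challenge in NAc and 3 in dStri, and 9 for the history in dStri. With library quality weights they were 18 for H24 against S24 in NAc, 9 for SH against SS in PFC, and for the challenge 6 in NAc and 94 in PFC (47 of them shared).

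With oligodendrocyte and choroid plexus scores as covariates, SH against SS gave 0 in NAc and 1 in PFC, and the challenge 23 in PFC (21 shared). With the inflammation score, SH against SS gave 0 in NAc and 0 in PFC, and the challenge 0 in NAc and 8 in PFC (8 shared). With the meningeal score, H24 against S24 gave 3 in NAc, SH against SS 0 in NAc, 1 in PFC and 3 in dStri, and the challenge 4 in NAc, 9 in PFC (8 shared) and 2 in dStri.

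Leaving out 1 library at a time, each 30 d library of NAc, PFC and dStri and HH mouse 7 of VTA, kept 634 counts within 1.5 times and moved 52. The challenge in PFC ran from 42 to 75 genes (75 without SH mouse 29, 74 without HH mouse 5, 73 without SH mouse 4), in NAc from 1 to 5 (5 without SH mouse 4 or SS mouse 22, 3 without SH mouse 17, 2 without HH mouse 1, HS mice 14 or 20, SH mouse 24 or SS mouse 8) and in dStri from 1 to 2 (2 without HH mice 1 or 18, SH mouse 17 or SS mice 8 or 22). SH against SS ran from 2 to 15 in PFC (15 without SS mouse 22, 8 without SH mouse 29, 7 without HH mouse 5, 6 without SS mouse 8, 5 without HH mice 1 or 25, HS mice 3 or 14 or SS mouse 15) and from 0 to 2 in NAc (2 without SS mouse 6, 0 without HH mouse 1, HS mice 3 or 11, SH mice 10, 19, 24, 27 or 30 or SS mice 8, 15, 22, 26 or 28). HH against SS ran from 0 to 4 in PFC (4 without HS mouse 13, 3 without HH mice 5 or 25, HS mouse 11, SH mouse 17 or SS mouse 8, 2 without HS mice 2 or 14, 1 without HS mouse 20 or SS mouse 6) and from 0 to 1 in NAc, as did HH against SH (1 without SS mouse 26) and HS against SS (1 without SS mouse 32).

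At an unadjusted p under 0.05 with a fold of at least 1.3, the counts, to 2 significant digits, for H24 against S24, SH, HS and HH against SS, HH against SH, the interaction, the challenge and the history, in that order, were 8.0e+02, 3.9e+02, 3.6e+02, 2.7e+02, 3.9e+02, 3.5e+02, 2.3e+02 and 3.5e+02 in BLA, 4.0e+02, 4.0e+02, 3.0e+02, 4.1e+02, 2.6e+02, 3.1e+02, 3.4e+02 and 2.4e+02 in NAc, 2.0e+02, 5.2e+02, 3.4e+02, 5.8e+02, 4.3e+02, 3.7e+02, 4.7e+02 and 4.2e+02 in PFC, 3.7e+02, 3.5e+02, 3.3e+02, 3.3e+02, 4.8e+02, 5.7e+02, 3.6e+02 and 3.0e+02 in VTA, 2.9e+02, 4.7e+02, 3.2e+02, 3.2e+02, 3.8e+02, 3.9e+02, 4.6e+02 and 2.7e+02 in dStri, and 4.1e+02, 2.3e+02, 2.5e+02, 8.5e+02, 9.5e+02, 5.0e+02, 2.2e+02 and 5.6e+02 in vHPC.

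With an estimated correlation camera called 0 lists for H24 against S24, 0 for SH and 0 for HS against SS, 1 for HH against SS, 0 for HH against SH, 0 for the interaction, 2 for the challenge and 0 for the history. Among genes of at least 5 CPM the median r between regions was 0.0586 for SH against SS, with a permutation p of 0.24, and -0.000166 for HH against SH. With the SS mice split between the comparisons the median r of SH and HH against SS over the regions was -0.0218.

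Turns of direction are given for single genes whose main value was at least 1 SE from 0, and these did not pass in either setting. Turns from values nearer to 0, such as Oprm1 in VTA for HH against SH (0.1779, and -0.07671 without HH mouse 7), are not listed. With the mouse set, Oprm1 in vHPC stood at 0.01499 for HH against SS and 0.05165 for the history. With the meningeal score, Trh in VTA stood at 0.1992 for H24 against S24. By DESeq2, Slc6a3 in BLA stood at -1.035 for HH against SH and -0.4041 for HH against SS. In VTA, mt-Nd5 for HH against SS stood at -0.008217 by DESeq2, -0.06021 with composition scores, -0.1664 with the inflammation score and -0.001482 without HH mouse 7, and mt-Nd6 at -0.008805 with composition scores and -0.2107 with the inflammation score, and for the history at -0.1549 with the inflammation and -0.08399 with the meningeal score.

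Ttr in BLA stood at -0.2416 for H24 against S24 with composition scores and -0.4288 for HH against SH with the inflammation score. For SH against SS it stood at 0.6932 by DESeq2, 1.742 with the inflammation and 0.4756 with the meningeal score and 0.8059 without libraries that stand apart. For the challenge these were 0.2424, 0.1574, 0.3437 and 0.3009, with 0.06976 under composition scores, which gave -0.05892 for the history. For the interaction they were -0.9017, -3.168, -0.2637 and -1.01, with -0.2568 under quality weights. Ttr in PFC stood at 0.06992 for H24 against S24 with quality weights and -0.3541 for HS against SS with composition scores, and in dStri at -0.4162 for HH against SS with composition scores. In vHPC it stood at -0.2088 with composition and -0.1838 with meningeal scores for HH against SH, -0.09761 and -0.1659 for the history, and -0.2224 and -0.03574 for the interaction, which was -0.5355 by DESeq2.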

Other observations

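The tests of mouse-level genes and of 1 value per mouse were chosen after the results were seen, while the prediction on body temperature was written before its test. For some genes the deviation from the group mean was partly shared by the regions of a mouse. Among 18630 genes the median share of group-centred variance between mice, over 6 regions of 49 mice, was 0.0108, and 157 genes exceeded 0.3. Antigen presentation and interferon-induced genes were among them (H2-K1 0.707, H2-D1 0.638, B2m 0.51, Gbp4 0.609, Gbp2 0.551), with genes of activated endothelium (Vwf 0.647, Sele 0.612, Selp 0.556), the acute-phase gene Lcn2 (0.61), growth hormone (Gh 0.776), Btaf1 (0.849) and Banp (0.773). These groups were read off the 157 genes and not tested for enrichment. The nearest fixed lists had shares of 0.291 (interferon and inflammation genes) and 0.245 (endothelial and mural markers). Acer2, the gene that fell with the challenge in PFC and NAc, had a share of 0.627, so its values in several regions of 1 mouse are not independent.

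By list, the share was 0.656 for heat shock and chaperone genes, 0.57 for blood markers, 0.45 for glucocorticoid-responsive genes, 0.245 for endothelial and mural markers, 0.223 for microglia markers and 0.193 for immediate early genes, against -0.00877 for meningeal and -0.0431 for choroid plexus markers. Heat shock genes (Dnajb1 0.635, Hspa1b 0.575) and the cold-inducible genes Rbm3 (0.615) and Cirbp (0.539) also had high shares.

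A candidate explanation is that the mice differed in body temperature, which would set the cold-inducible against the heat shock genes. Over mouse means, Rbm3 and Cirbp went against Hspa1a, Hspa1b, Dnajb1 and Hsph1 with Spearman's rho = -0.591 (permutation p = 2e-05, 49 mice; r = -0.582, and -0.608 without 2 mice). This may reflect temperature but stays a hypothesis, since the genes were picked after a scan of all genes and no temperature was recorded in the labels.

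With 1 value per mouse, the mean over its regions, limma called 3 genes for the challenge: Dusp6 (log2 0.23, adjusted p = 0.0026, higher in 15 of 15 mice), Stk40 (0.15, adjusted p = 0.00995, 15 of 15) and Fosb (0.32, adjusted p = 0.0116, 14 of 15). The other contrasts called 0 with limma, with 723 to 936 genes at an unadjusted p under 0.05; DESeq2 and edgeR were not run on these means.

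Over the 36 planned tests per list, camera with the preset correlation called heat shock and chaperone genes in 21, immediate early genes in 15, meningeal fibroblast markers in 15, glucocorticoid-responsive genes, endothelial and mural markers, striatal projection neuron markers and cortical and hippocampal excitatory neuron markers in 14 each, oligodendrocyte markers in 13, ependymal markers in 12, blood markers in 11, glutamate receptor genes in 10 and interferon and inflammation genes in 8. Circadian clock, dopamine signalling, choroid plexus and microglia lists were called in 7 each, GABA signalling genes, DNA and chromatin modifiers, oligodendrocyte precursor and dopamine neuron markers in 6 each, neuropeptide genes in 5, opioid peptides and receptors and astrocyte markers in 4 each, and midbrain, thalamic and hypothalamic neuron markers in 1. Extracellular matrix and perineuronal net genes, hypoxia and glycolysis genes and cortical interneuron markers were called in 0. With an estimated correlation 1 of all these calls held, that of immediate early genes for HH against SS in PFC. Genes shared with another list numbered 11 of the 20 dopamine signalling genes, 9 of the 15 striatal projection neuron markers and 5 of the 15 dopamine neuron markers, against 1 of the 30 immediate early genes and 0 of the 12 meningeal markers.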
